A study of Mus musculus with 73 samples.

How the data were processed

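The samples were male mouse embryonic stem (ES) cells of the line E14Tg2a and clones of it with edits in the X-inactivation centre (Xic), the region of the X chromosome that holds Xist and its antisense gene Tsix. Per the labels' protocols, the cells grew without feeder cells on gelatin in serum with leukemia inhibitory factor. Of 73 samples, 28 were analysed: 12 of RNA-seq, 10 of 5C and 6 of RNA antisense purification (RAP) of Xist. The other 20 samples of 5C, 22 of Capture-C and 3 RAP inputs were not analysed here. The genotype labels name the RNA and RAP alleles 40kb [Tsix-Xist] and 70kb [Xite-Jpx], and the series' description speaks of inversions and deletions without saying which these alleles are. What the letters E and C of XiteE and XiteC stand for is not given in the sources used here. Groups were taken from the sample titles.

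RNA-seq libraries were made with a stranded kit for polyadenylated RNA, per the labels' protocols. The deposited RNA table holds whole-number counts per gene, and STAR, edgeR and the build mm9 are named in the submitters' processing notes. The strand setting of the counting is not given in the sources used here, and Xist and Tsix overlap on opposite strands, so the counts of both carry that doubt. Library totals ran from 34514493 to 46605508 counts. Of 37310 gene identifiers, 32620 matched a symbol and 28097 a chromosome through the gene tables used here, the second of which is of assembly GRCm38.p6 and served for names, chromosomes and gene order, with none of its positions printed. The symbols C77370, Cnbp2, Oct6 and Sc4mol were matched through synonyms to Nexmif, Zcchc13, Pou3f1 and Msmo1. Linx, Xite, Jpx, Sox1, Rhox5 and several members of the imprinted, 2-cell-like, cholesterol and ribosomal lists were not analysed here.

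Gene counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the tool's default filter on low counts, a quasi-likelihood F test on 1 fit of the 12 libraries with a mean per group, and Benjamini-Hochberg adjustment with a threshold of 0.05. After the filter 16636 genes were tested, 15683 of them with a chromosome. Each allele was compared with the wild-type libraries that its labels name as corresponding. The fit had 8 residual degrees of freedom and a biological coefficient of variation of 23.8%. Levels (CPM) are counts scaled to a common library total, given as mean ± SD, and SE is the standard error of a log2 fold change. Gene lists were tested with camera of limma 3.58.1, at a preset correlation of 0.01 and with the correlation estimated, and with fry. Median differences between X-linked and autosomal genes were taken over the same fit. DESeq2 1.42.0 was the alternative tool. On simulated counts for the 40kb comparison with 200 changed genes among 16376, the fit recovered 41% of 2-fold and 89% of 4-fold changes with 8 false calls.

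The genes, lists, tests and most alternatives were fixed before the data were examined. Named genes are the measured Xic genes of both neighbour lists; the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 counts, the same sign in both clones and every allele library beyond both wild-type libraries; up to 3 called members of each list with the smallest adjusted p; and Xist and Tsix. A gene that this rule names is not reported here. Predicted genes and pseudogenes were left out of the second part of that rule, which excluded 31 of the 928 genes that met it otherwise. Of 5C bin pairs up to 3 rises and 3 falls with the smallest adjusted p per genotype were to be named, and of RAP windows the 3 largest rises and falls and the window of the Xic. The lists were Tsix-side and Xist-side neighbours in the Xic, flanking X genes, naive pluripotency, formative and primed pluripotency, primitive endoderm, mesoderm and primitive streak, neural, 2-cell-like, fibroblast, trophoblast, imprinted, germline, p53 targets, regulators of Xist, Y-linked, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and amino acid stress, ribosomal proteins and housekeeping. A marker score per library, chosen after the data were seen, is the mean log2 level of the 25 fibroblast and trophoblast genes, centred per gene.

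5C counts ligation products between forward and reverse primers on restriction fragments of a chosen region. The deposited 5C files hold raw counts per primer pair, and Bowtie2 and mm9 are named in the submitters' processing notes. The deposited primer lists give fragment positions (unit other than a measurement) on mm9: 511 forward and 528 reverse primers covered X:98831149-103425147, 4.59 Mb, and 26 of each kind lay on chromosome 5. Totals ran from 16267499 to 23928188 counts. Counts were summed over pairs of 30 kb bins. In edgeR 10476 pairs with a mean of at least 10 counts were tested with the library total as offset. The 1 fit of the 10 libraries had 5 residual degrees of freedom and a biological coefficient of variation of 55.5%. Wild-type replicate 2 and XiteE-inv replicate 2 (B101 in their names) held 15.0 and 14.5% of X bin-pair counts at 900 to 4600 kb, against 24.7 to 29.8% in the other libraries (B100). This split lies within groups and enters that spread. A fragment was called lost when its share of a library was under 10% of the wild-type mean in both libraries of a genotype and it had at least 100 wild-type counts. Domain borders were minima of an insulation score of the summed wild-type libraries over 5 bins on each side, at least 0.2 deep on the log2 scale. The crossing percent is the counts between the 150 kb on either side of a border over the counts within those sides. Fragments lost in either deletion were left out of it in all libraries. On simulated counts for the XiteC-del comparison with 200 changed bin pairs among 10476, the fit recovered 0% of 2-fold and 4% of 4-fold changes with 2 false calls, so most 4-fold changes of single bin pairs would be missed.

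RAP pulls down Xist RNA with the chromatin it touches. The deposited RAP table gives 164 windows of 1 Mb of the X chromosome with raw counts and, per the file headers, a normalized value, read here as the ratio of pull-down over input from the authors; BWA 0.5.9, Picard and mm9 are named in the submitters' processing notes. Raw totals ran from 11962 to 58624 counts. Of the raw values of a library 95.1 to 100% were even, for which the sources used here give no reason, so edgeR, as an alternative added after the data were seen, was run on raw counts divided by 2. Raw over normalized values of the 2 pull-downs of a cell line differed by a constant factor over all 164 windows, so both pull-downs share an input profile. The unit was unknown when the design was fixed, and the ratios were tested with limma on log2(ratio + 0.5), for which fold changes of low windows are understated, with 3 residual degrees of freedom. The table also has 2 columns that match no sample, which were not used. On simulated data for the 40kb comparison with 40 of 164 windows changed, limma recovered 0% of 2-fold and 85% of 4-fold changes with 0 false calls. Single values per library were compared with an exact two-sided permutation test, which for 2 against 2 libraries cannot go below p = 0.33.

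Samples of the 70kb set that share a replicate number deviated together in 12673 genes (correlations 0.851 and 0.324 between wild type and the clones, and 0.27 between the clones). The numbers, which in this set go with the B numbers in the sample names, therefore pair these samples. A fit with the number as a block was an alternative. Alternatives covered the scaling, the filters, the tool, blocks by replicate number or by the sequencing code in the sample names, single clones, other control libraries, bin sizes, pseudocounts and leaving out each library in turn. Independence of the replicates is not stated in the labels, so p-values measure only the spread between these samples, which may be technical, and the 4 libraries of an RNA allele are 2 clones with 2 replicates each. Numerical work and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.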

Results

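Male mouse ES cells carry a single X chromosome, on which Tsix is active and the silencing RNA Xist is nearly off. The X-inactivation centre (Xic) that holds both genes was edited to ask how its division into a domain with Tsix and a domain with Xist bears on the expression of both. RNA-seq covered 4 libraries (2 clones with 2 replicates each) of the 40kb [Tsix-Xist] allele and 4 of the 70kb [Xite-Jpx] allele, each set with 2 wild-type libraries of its own, all of undifferentiated cells. 5C covered 2 libraries each of wild type and of the genotypes XiteE-del, XiteE-inv, XiteC-del and XiteC-inv, named for Xite, an enhancer of Tsix. RAP of Xist covered 2 pull-downs each of wild type and of 1 clone of each RNA allele. RNA libraries held 34514493 to 46605508 counts, 5C libraries 16267499 to 23928188 and RAP libraries 11962 to 58624.

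Xist (ENSMUSG00000086503.1), the RNA that coats and silences the X chromosome, was 51.7-fold higher in the 40kb libraries than in their wild type. It rose from 0.768 ± 0.0477 CPM (SD, n = 2) to 39.9 ± 30.5 CPM (SD, n = 4), a log2 fold change of 5.69 (SE 0.79, adjusted p = 0.0162, edgeR). Both clones lay above both wild-type libraries, at 82 and 42.4 CPM in clone 1 and 14.7 and 20.4 CPM in clone 2 against 0.801 and 0.734 CPM. Tsix (ENSMUSG00000085715.1) had 15.5 ± 5.29 CPM (n = 2) in wild type and 18.2 ± 4.05 CPM (n = 4) in the 40kb libraries, a log2 fold change of 0.23 (SE 0.3, adjusted p = 0.682, edgeR), which was -0.09 without wild-type replicate 2 and with the marker score as a covariate. The call of Xist was lost without wild-type replicate 1 (adjusted p = 0.0747) or replicate 2 (0.159), against the wild type of the 70kb set (log2 fold change 4.69, adjusted p = 0.0796). It was also lost with counts summed per clone (0.0559) and with the marker score as a covariate (3.95, SE 0.86, unadjusted p = 0.000663, adjusted p = 1, edgeR). Over these and the other alternatives its log2 fold change stayed between 3.95 and 6.33.

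In the 70kb libraries Xist had 5.99 ± 1.87 CPM (n = 4) against 1.54 ± 1 CPM (n = 2) in their wild type. All 4 libraries (8.75 and 5.37 CPM in clone 1, 4.63 and 5.22 CPM in clone 2) lay above both wild-type libraries (2.25 and 0.832 CPM). The log2 fold change of 1.95 (SE 0.65) did not pass the threshold (adjusted p = 1, edgeR). It was 2.84 without wild-type replicate 1, 1.41 without replicate 2 and 2.96 against the wild type of the 40kb set, the lowest and highest values over the alternatives being 1.41 and 2.96. Tsix had 12.3 ± 2.86 CPM (n = 4) against 15.7 ± 5.63 CPM (n = 2), a log2 fold change of -0.35 (SE 0.3, adjusted p = 1, edgeR), which was 0.07 without wild-type replicate 1. The difference between the effects of both alleles on Xist was 3.74 on the log2 scale (SE 0.91, adjusted p = 0.169, edgeR interaction).

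**Figure D1:**
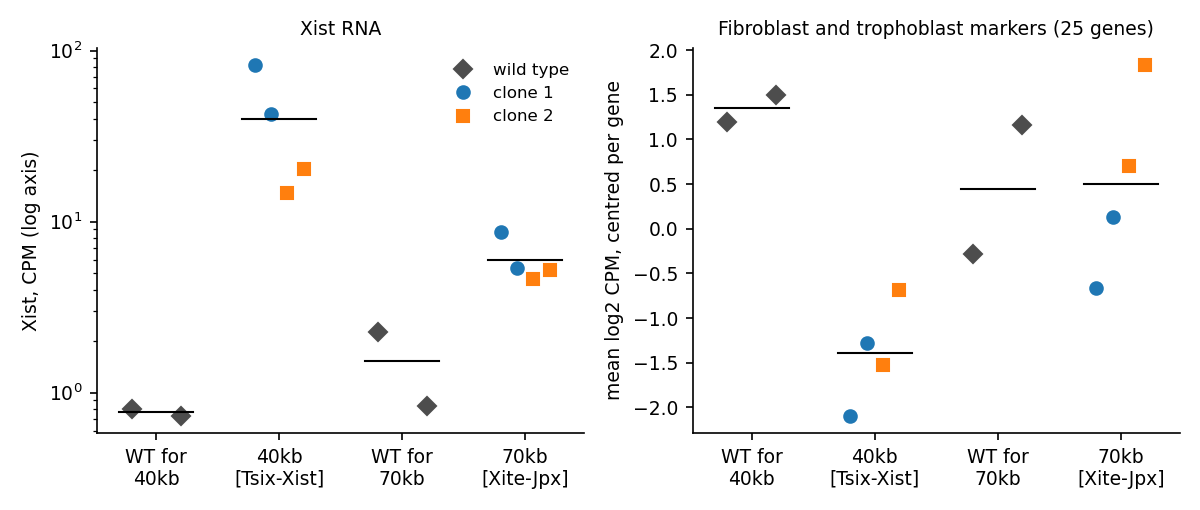
Left, Xist in CPM on a log axis, and right, the marker score (mean log2 CPM of 25 fibroblast and trophoblast genes, centred per gene) in each of the 12 RNA libraries; lines are group means, diamonds wild type, circles clone 1 and squares clone 2. The 40kb libraries sit between 14.7 and 82 CPM of Xist and at marker scores from -2.09 to -0.68, and their wild type at 0.801 and 0.734 CPM and at scores of 1.197 and 1.5.

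Rlim and Ftx, neighbours of Xist on its side of the Xic, were lower in the 40kb libraries. Rlim, a ubiquitin ligase that activates Xist, fell from 306 ± 19.4 to 158 ± 12.3 CPM (1.94-fold lower, adjusted p = 0.0162, edgeR), with log2 fold changes of -0.96 and -0.95 in the clones taken alone. Ftx, a noncoding RNA gene, fell from 14.4 ± 1.02 to 5.9 ± 1.74 CPM (log2 fold change -1.29, SE 0.25, adjusted p = 0.0201). With the rise of Xist, 4 of the 4 tested Xist-side genes were called, and 4 when adjusted over the list alone. On the Tsix side 1 of 5 tested genes was called and 2 when adjusted over the list alone, and the set was called lower by fry (adjusted p = 0.0364) but not by camera (adjusted p = 0.102). Cdx4, a caudal-type homeobox gene, fell from 2.55 ± 0.504 to 0.17 ± 0.0988 CPM (14.9-fold lower, log2 fold change -3.90, SE 0.56, adjusted p = 0.0162). Nap1l2 had a log2 fold change of -1.16 (adjusted p = 0.0686), Chic1 of -0.40 (0.212) and Tsx of 0.44 (0.538). Among 14 tested flanking X genes 1 was called and 2 when adjusted over the list alone. The 1 called over all genes was Phka1, a phosphorylase kinase subunit, with a log2 fold change of -0.78 (adjusted p = 0.0346). With the B code as a block Ftx had an adjusted p = 0.0524 (log2 fold change -1.24, edgeR). With counts summed per clone the calls of Rlim, Ftx and Cdx4 had an adjusted p = 0.0559 each. These calls were lost without wild-type replicate 1 (adjusted p from 0.0747 to 0.0814) and without replicate 2 (0.159 to 0.194), and against the wild type of the 70kb set (log2 fold changes -0.60, -0.50 and -2.54). With the marker score as a covariate the log2 fold change of Rlim was -0.95, of Cdx4 -2.02 and of Ftx -0.52, all with adjusted p = 1.

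Genome-wide, 1070 of 16636 genes were called in the 40kb comparison, 943 of them lower and 127 higher, and DESeq2 called 1874. Among the genes chosen by the naming rule the largest falls were of Pcdh7 (log2 fold change -5.51), a protocadherin, Tmprss2 (-5.31), a serine protease, Vnn1 (-5.29), Klhl30 (-5.29), Ccdc80 (-5.08), Pappa (-5.04), Col1a2 (-4.96) and Igf2 (-4.85). Igf2, an imprinted growth factor gene, fell from 70.7 ± 10.9 to 2.46 ± 2.01 CPM (SE 0.79, adjusted p = 0.0175, edgeR). Beside Xist, the largest rises by that rule were of Spink10 (4.28), Srgn (2.99), Myo1f (2.88, from 2.42 ± 0.0863 to 17.8 ± 7.24 CPM), Fkbp6 (2.78), Sema5b (2.50), Myo1g (2.38) and Catsperz (2.25), with adjusted p from 0.0167 to 0.046. In 36.2% of genes all 4 allele libraries lay beyond both wild-type libraries, and in 5.48% in the 70kb comparison, where chance gives 13.3% for libraries that vary independently. The count was 0 without either wild-type library (2637 genes at an unadjusted p under 0.05 without replicate 1, 1968 without replicate 2), 0 against the wild type of the 70kb set (2134) and 0 with the marker score as a covariate (303), all in edgeR. With that covariate Pcdh7, Ccdc80, Pappa and Col1a2 had log2 fold changes above 0 (0.65, 0.39, 0.20 and 0.52), and Col1a2 is itself part of the score. The score sets the 40kb libraries (-2.09 to -0.68) apart from their wild type (1.197 and 1.5). A fit with the covariate therefore cannot tell the allele from what the score measures. The number of called genes was 527, 277 and 279 without clone 1 replicate 1, clone 1 replicate 2 and clone 2 replicate 1, 2476 in clone 1 alone and 530 in clone 2 alone. With the B code as a block it was 357, and 16 of the 47 called genes that the naming rule took were called. Clone 1 replicate 1 and clone 2 replicate 1 share their code with no other library, so that block takes them out of the comparison. Fewer calls under it can come from this loss as well as from the code.

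Markers of other cell types fell together in the 40kb libraries. Of 15 tested fibroblast genes 9 were called, all lower, and 11 lower when adjusted over the list alone, with a median log2 fold change of -4.04. Tagln and Acta2, of smooth muscle and fibroblasts, fell from 199 ± 55.3 to 10.9 ± 11.1 CPM and from 60.6 ± 3.2 to 2.29 ± 2.37 CPM, and the collagen gene Col1a2 from 14 ± 3.53 to 0.458 ± 0.525 CPM. Dcn was also called (-3.44, adjusted p = 0.0279). Of 10 tested trophoblast genes 6 were called, all lower, and 8 lower over the list alone, median -3.43. The simple-epithelium keratins Krt8, Krt18 and Krt19 fell from 243 ± 62.5 to 11.4 ± 8.25 CPM, from 194 ± 28.1 to 12.2 ± 5.92 CPM and from 48.7 ± 8.28 to 4.58 ± 1.92 CPM. Of 13 tested mesoderm and primitive streak genes 4 were called, all lower, and 8 lower over the list alone, among them Wnt3 (-4.47, adjusted p = 0.0175), Cdx2 (-4.35, 0.0235), which is also on the trophoblast list, and Kdr (-1.44, 0.0237). Camera at the preset correlation called the fibroblast, trophoblast and mesoderm lists lower (adjusted p = 9.72e-07, 3.56e-05 and 6.89e-05), and each had an adjusted p = 0.424 with an estimated correlation. Fry, which does not compare a list with other genes, called them lower as well (adjusted p = 0.0364, 0.0299 and 0.0364). With the B code as a block, and so with fewer 40kb libraries, 0 fibroblast, 1 trophoblast and 1 mesoderm gene were called. The marker score was 1.197 and 1.5 in the wild-type libraries of this set, -2.09, -1.28, -1.52 and -0.68 in the 40kb libraries, and -0.28 and 1.165 in the wild-type libraries of the 70kb set.

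Some pluripotency genes were higher and others lower. Among 20 tested genes of naive pluripotency 3 were called, all higher, and 11 higher and 1 lower when adjusted over the list alone. Nr0b1, a nuclear receptor, rose from 76.4 ± 21.1 to 172 ± 10.8 CPM, Fgf4 from 116 ± 45 to 216 ± 14.6 CPM and Dppa2 had a log2 fold change of 0.70 (adjusted p = 0.046, 0.0488 and 0.0392, edgeR). With the marker score as a covariate no naive gene was called and the log2 fold change of Nr0b1 turned in sign. The list had a median log2 fold change of 0.572 and was called higher by camera (adjusted p = 1.67e-05), with an adjusted p = 0.424 with an estimated correlation, and higher by fry (adjusted p = 0.0364). Of 14 formative and primed genes 2 were called, both lower, and 4 over the list alone (1 higher). Fgf5 fell from 12.6 ± 6.2 to 2.22 ± 1.38 CPM and the kinase gene Pim2 from 118 ± 36.7 to 39.3 ± 15.7 CPM. Of 18 primitive endoderm genes 4 were called and 8 over the list alone (3 higher). Cited1 (-3.17), Dab2 (-2.0) and the collagen gene Col4a2 (-2.08) were lower and Srgn, a proteoglycan gene, was higher at 2.99. Median and mean of this list differed in sign (0.061 and -0.162). Of 10 neural genes 1 was called, and 1 over the list alone. Nes, an intermediate filament gene, fell from 92.6 ± 6.78 to 17.3 ± 8.91 CPM. None of 12 tested 2-cell-like genes was called, and 0 over the list alone (edgeR; 1 by DESeq2), though their median was 1.526 with 12 of 12 above 0 (camera adjusted p = 0.00384, adjusted p = 0.661 with an estimated correlation). With the sequencing code as a block 1 endoderm and 2 neural genes were called. The calls of the lists named here and above were all lost without either wild-type library of this set.

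Imprinted genes were lower as well: of 29 tested 6 were called, all lower, and 10 lower and 1 higher over the list alone, with Igf2 (-4.85), Sgce (-1.78) and Peg12 (-1.73) called with the smallest adjusted p (camera adjusted p = 0.00357, adjusted p = 0.424 with an estimated correlation, fry adjusted p = 0.0299). Hormad1, a meiosis gene, was the 1 called gene of 17 germline genes (1 over the list alone) and rose from 13 ± 1.61 to 50.2 ± 33.8 CPM. Clone 1 replicate 1 was at 100.7 CPM and the other 40kb libraries at 28.6 to 36.7 CPM. Of 20 p53 targets 2 were called lower, Perp (-1.64) and Btg2 (-1.23), and 6 over the list alone, 1 of them higher (camera adjusted p = 0.0474, adjusted p = 0.661 with an estimated correlation). Of 22 regulators of Xist 2 were called lower, Rlim and the Polycomb gene Pcgf5 (-1.19), and 4 over the list alone, 2 of them higher. Among 21 glycolysis and hypoxia genes Pfkp, a phosphofructokinase, was the 1 called and rose from 256 ± 23.2 to 508 ± 132 CPM. Among 16 stress genes Atf3 (-2.25) and among 12 housekeeping genes B2m (-1.43, from 29.4 ± 1.03 to 10.9 ± 3.04 CPM) were the only calls, with 1 gene of each of these lists over the list alone. Over all genes 1070 of 16636 were called. The calls in the germline, p53, Xist regulator, glycolysis, stress and housekeeping lists are near that share, as are those among flanking X and neural genes. They do not set these lists apart. With the B code as a block, and so with fewer 40kb libraries, 0 germline, 1 Xist regulator and 0 housekeeping genes were called. Of 5 Y-linked genes, 19 cholesterol genes and 28 ribosomal protein genes 0 were called in edgeR, 0 over the list alone, and DESeq2 called 0, 1 and 1. All 28 ribosomal protein genes had log2 fold changes above 0, with a median of 0.331 (camera adjusted p = 9.72e-07, adjusted p = 0.606 with an estimated correlation).

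X-linked genes had a lower median than autosomal genes in the 40kb libraries. The median log2 fold change of 657 tested X-linked genes was -0.033 and their mean -0.235, and their median lay 0.091 below that of 15017 autosomal genes (X minus autosomes -0.091). Single autosomes lay between -0.078 (chromosome 8) and 0.041 (chromosome 7), and in clone 1 alone chromosome 8 was at -0.155, farther from 0 than the X. Of the X-linked genes 87 were called (13.2% of the tested), 85 of them lower, and of the autosomal genes 965 (6.43%), 848 of them lower. When adjusted over the list alone, 108 X-linked genes were called and 7 of them were higher. Camera gave p = 0.00587 for a lower X, which was lost with an estimated correlation (p = 0.125, adjusted p = 0.438 with an estimated correlation), and fry called the X-linked genes lower (adjusted p = 0.0375). With an estimated correlation the lower X passed the threshold under 4 other settings: with the B code as a block (X minus autosomes -0.148, p = 0.0168), with the marker score as a covariate (-0.162, p = 0.0247), with a mean of at least 50 counts (-0.125, p = 0.0463) and without clone 1 replicate 1 (-0.15, p = 0.00791). The X minus autosome difference was -0.166 in clone 2 and -0.028 in clone 1. The difference between the clones was not tested. Library by library it was 0.061 and -0.164 in clone 1 and -0.2 and -0.154 in clone 2.

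No gene was called in the 70kb comparison (edgeR, with 100 genes at an unadjusted p under 0.05, and 3 calls by DESeq2). Chance would give about 832 such genes, so the test was conservative here. A lack of calls in it does not show a lack of effect. Among the other Xic genes, Tsx, first found in testis, had 0.143 ± 0.0413 CPM against 0.564 ± 0.0115 CPM (log2 fold change -1.95, SE 0.43, adjusted p = 1, edgeR). Ftx had 13.8 ± 2.99 CPM against 8.32 ± 0.767 CPM (0.73, SE 0.27, adjusted p = 1), and Cdx4 and Rlim had log2 fold changes of -0.73 and -0.02. Against the wild type of the 40kb set Ftx was at -0.06, Cdx4 at -2.09 and Rlim at -0.38, and against all 4 wild-type libraries Ftx was at 0.28 and Cdx4 at -1.56. Without wild-type replicate 1 and 2 Cdx4 was at -1.35 and 0.38. The 5 tested Tsix-side genes, with a median of -0.475 and 0 above 0, were called lower as a set by camera (adjusted p = 4.16e-07, adjusted p = 0.0431 with an estimated correlation), with 1 gene called over the list alone. Fry did not call this set (adjusted p = 0.15). Of the 4 Xist-side genes 2 were called higher over the list alone, and the 0 called genes of the other lists became 0 over each list alone except 1 of 657 X-linked genes. Camera at the preset correlation also called p53 targets higher (20 of 20 above 0, median 0.259, adjusted p = 1.9e-06) and the formative, cholesterol, primitive endoderm and glycolysis lists lower and the 2-cell-like list higher (adjusted p = 0.000266, 0.00307, 0.02, 0.0318 and 0.0318). None of these held with an estimated correlation (adjusted p = 0.348 to 0.888). The X-linked genes differed from autosomal genes by -0.018 (camera, adjusted p = 0.5 over the lists).

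The difference between the effects of both alleles was not called for any gene (edgeR, with 2128 genes at an unadjusted p under 0.05, and 399 calls by DESeq2). Its values were -2.02 for Ftx (SE 0.37), -0.93 for Rlim (SE 0.2), -3.17 for Cdx4 (SE 0.82) and 2.39 for Tsx (SE 0.6). Line names and B codes of the wild-type libraries of both sets also differ in the labels. These libraries gave 0 calls against each other (394 at an unadjusted p under 0.05 where chance gives about 832, 0 by DESeq2). Between them the 2-cell-like genes had a median of -1.236 in the 40kb set minus the 70kb set (0 of 12 above 0) and the fibroblast, trophoblast and mesoderm genes medians of 0.632, 1.007 and 0.834 (camera adjusted p = 0.000167, 0.02, 0.0231 and 0.0318). The naive pluripotency and Y-linked genes had medians of -0.161 and -0.415 (camera adjusted p = 0.0318 and 0.0483). Each of these 6 lists had an adjusted p = 0.719 with an estimated correlation.

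The 5C libraries of the deletions lacked fragments at Xite, which checks their labels. In XiteE-del 2 fragments spanning X:100623271-100633845 (mm9, 10.6 kb) held at most 4.91% of their wild-type share of counts in both libraries. In XiteC-del 1 fragment at X:100636563-100639613 (mm9, 3.05 kb) held at most 3.61%. Next to these, X:100618973-100623270 held 13.5 and 14.4% of its wild-type share in the XiteE-del libraries. X:100633846-100636562 held 49.9 and 54.6% in the XiteC-del libraries. Both were over the bound and were kept. Both inversions kept these fragments, with 0 lost, and in XiteE-inv 9 fragments were under the bound in replicate 2 taken alone. The summed wild-type map had 18 borders, of which the one at X:100650000 (mm9), 16.4 kb from the lost fragments, as the nearest one, was taken as the border between the Tsix side (X:100440001-100650000) and the Xist side (X:100650001-100860000). No annotation of mm9 was used here, so fragments are given by position only.

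Contacts across the border between the Tsix and Xist domains made up a larger share of local contacts in both XiteC genotypes. The crossing percent was 9.89 ± 0.388 (SD, n = 2) in wild type, 16.1 ± 0.421 in XiteC-del and 14.6 ± 0.834 in XiteC-inv (n = 2 each), so 1.62 and 1.48 times the wild type. The XiteE genotypes had 11.2 ± 0.163 (XiteE-del) and 9.59 ± 1.73 (XiteE-inv, n = 2 each), and both XiteE-inv libraries carry the same clone name. The difference exceeded the spread between replicates in XiteC-del, XiteC-inv and XiteE-del, with an exact permutation p = 0.33 for each, the smallest this design allows. Over 300 kb the excess of XiteE-del was gone (ratio 1, exact permutation p = 1). Without the 30 kb bin of the edited site the values were 6.98 in wild type, 13.6 in XiteC-del and 8.36 in XiteC-inv. In the model of domain blocks, contacts between the Tsix and Xist sides had a log2 fold change of 0.50 in XiteC-del (SE 0.11, adjusted p = 0.53) and 0.38 in XiteC-inv (SE 0.11, adjusted p = 0.735). No block of 190 was called in any genotype (edgeR, with 2, 1, 1 and 7 blocks at an unadjusted p under 0.05 in XiteE-del, XiteE-inv, XiteC-del and XiteC-inv). With the B code as a block, which differs for 1 wild-type and 1 XiteE-inv library, the values were 0.60 (adjusted p = 0.000263) and 0.48 (0.00225). In that fit 3, 8 and 15 blocks were called in XiteE-del, XiteC-del and XiteC-inv, of which 0, 7 and 12 were lower. Borders from 15 kb bins, with the nearest one at X:100680000, gave 0.17 in XiteC-del and 0.39 in XiteC-inv (SE 0.15 each). TMM scaling gave 0.25 and 0.17 (SE 0.32 each). No block was called under either setting.

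**Figure D2:**
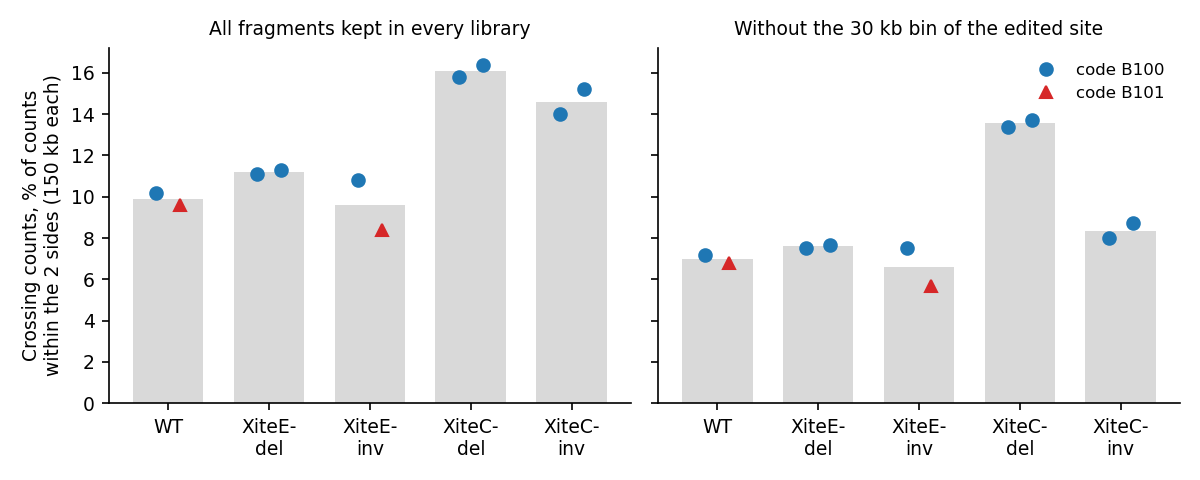
Counts that cross the border between the Tsix and Xist sides as a percent of counts within both sides, per 5C library (points, shaped by B code) with the mean of each genotype as a bar, for all kept fragments (left) and without the 30 kb bin of the edited site (right). XiteC-del averages 16.1% and XiteC-inv 14.6% against 9.89% in wild type, and 13.6% and 8.36% against 6.98% without that bin.

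In XiteC-inv the edited bin itself, X:100620001-100650000, lost contacts before the border at X:100650000 and gained contacts beyond it. It gained contacts with X:100800001-100830000, at 658 ± 52.7 against 250 ± 3.26 CPM (log2 fold change 1.39, SE 0.17, n = 2 each), and with X:101160001-101190000, past the end of the Xist side, at 555 ± 97 against 189 ± 10.3 (1.55, SE 0.2). It lost contacts with X:100560001-100590000, at 447 ± 31.6 against 1500 ± 286 (-1.75, SE 0.19), and with X:100470001-100500000, at 294 ± 28.5 against 821 ± 144 (-1.48, SE 0.19). These were the 4 called pairs of 10476 (adjusted p = 0.0474 each, edgeR), with 268 at an unadjusted p under 0.05 and 27 calls by DESeq2. Within 300 kb the median log2 fold change of the bin was -1.17 over 9 pairs before the border and 1.2 over 10 pairs beyond it. No pair was called with TMM scaling, with 60 kb bins or with a minimum of 50 counts, and leaving out single libraries gave 0 to 2 pairs. With the B code as a block 33 were called, 22 of them of the edited bin, 7 lower before the border and 15 higher beyond it, at any distance.

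In XiteC-del 0 of 10476 pairs were called (edgeR, 175 at an unadjusted p under 0.05, 0 by DESeq2), and 11 with the B code as a block. The main fit counts the difference between the codes as spread, so a lack of calls does not show a lack of change. Within 300 kb the edited bin of XiteC-del had medians of -0.66 before the border and -0.06 beyond it. A kept fragment of that bin held 49.9 and 54.6% of its wild-type share in XiteC-del, and its lower counts enter these medians. Neither XiteE genotype had a called pair in edgeR, but XiteE-del had 2 with the B code as a block and 5 with 15 kb bins. In XiteE-del 394 pairs had an unadjusted p under 0.05 and DESeq2 called 7, with medians of -0.28 and 0.05 for the edited bin. In XiteE-inv 239 had an unadjusted p under 0.05 and DESeq2 called 7, with medians of -0.07 and -0.02. Contacts within the Tsix side and within the Xist side differed from wild type by log2 fold changes of -0.31 to 0.06 over the 4 genotypes, with adjusted p from 0.72 to 1.

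**Figure D3:**
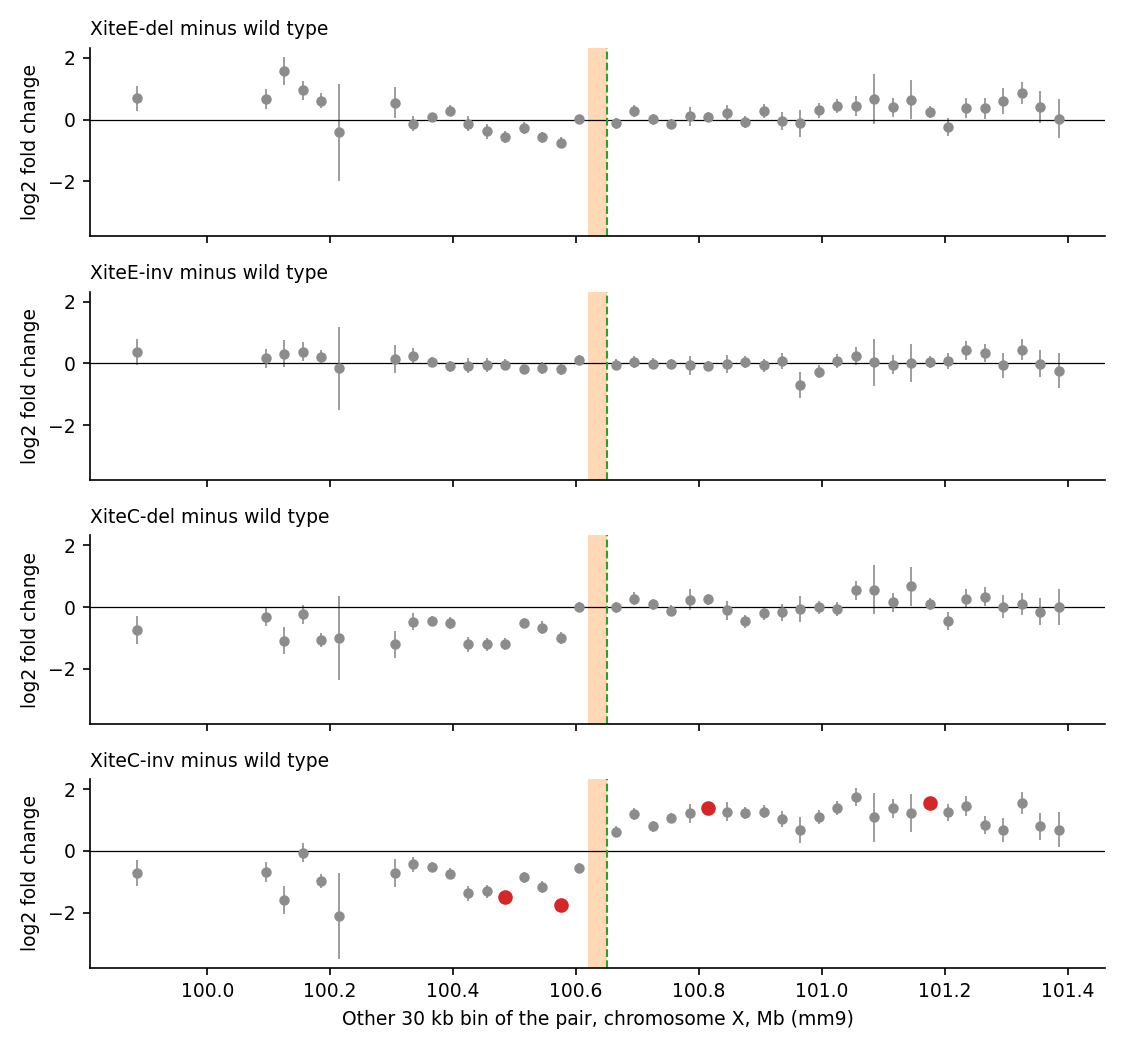
Log2 fold change (points, with SE bars) of contacts between the edited 30 kb bin (shaded) and each nearby bin in the 4 genotypes, by position on the X chromosome in Mb (mm9), with the border of the Tsix and Xist sides dashed and called pairs in red. In XiteC-inv the called pairs lie at -1.75 and -1.48 on the Tsix side and at 1.39 and 1.55 beyond the border.

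Xist pull-down was higher along most of the X chromosome in the 40kb clone. Of 164 windows 108 had more Xist pull-down over input than in wild type and 1 had less, with a median log2 fold change of 1.23 and 162 windows above 0 (limma, adjusted p under the threshold of 0.05). The largest rises were at X:144000001-145000000, 13.4 ± 7.83 against 1.57 ± 0.0837 (2.62, SE 0.47, adjusted p = 5.71e-06), at X:145000001-146000000, 14.5 ± 7.6 against 1.83 ± 0.517 (2.60), and at X:49000001-50000000, 9.45 ± 3.99 against 1.3 ± 0.593 (2.44). The window that holds the edited site, X:100000001-101000000, was the lower one, at 75.1 ± 0.763 against 319 ± 145 (-2.0, SE 0.47, adjusted p = 0.000486), and its share of the raw counts was 10.3 ± 2.68% against 52.4 ± 10.2% in wild type (n = 2 each). The mean ratio outside that window was 5.82 ± 1.95 in the 40kb clone and 2.22 ± 0.222 in wild type, 2.62-fold higher (exact permutation p = 0.33, the smallest this design allows). Centred on the median of each library 3 windows were called, but centring removes a rise shared by most windows whatever its cause. The height of the wide rise rests on the authors' scaling to input, and both pull-downs of a line share 1 input. The count was 29 and 66 without wild-type replicate 1 and 2, and 11 without the second 40kb pull-down.

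In the 70kb clone 0 of 164 windows were called (limma, 7 at an unadjusted p under 0.05, 0 by edgeR on raw counts divided by 2). The window of the Xic had a ratio of 247 ± 36.4 (log2 fold change -0.30, SE 0.47, adjusted p = 0.925). Its share of raw counts was 45.4 ± 10.1%, and the mean ratio outside it was 2.58 ± 0.63 (n = 2). The 40kb and 70kb pull-downs were each compared with wild type and not with each other.

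**Figure D4:**
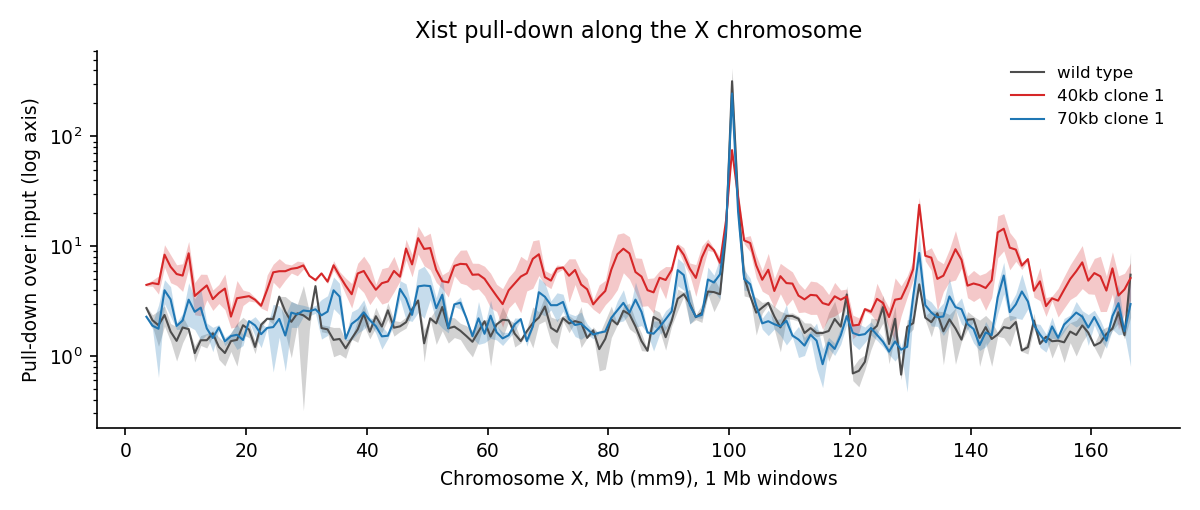
Xist pull-down over input (log axis) in 1 Mb windows along the X chromosome (Mb, mm9), with the mean of both pull-downs as a line and their range shaded, for wild type, 40kb clone 1 and 70kb clone 1. The fitted log2 fold change of the 40kb clone is above 0 in 162 of 164 windows, and at the window of the Xic the ratio is 75.1 against 319 in wild type.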

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

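The test for single libraries that stand apart was fixed before the data were examined, and no explanation was tested. Among 62 groups of 4 libraries, 4 had a library past Dixon's value of 0.829, where chance gives about 1 in 20 groups. All 4 were of the 40kb library of clone 1 replicate 1. There Nap1l2 was at 2.49 CPM against 1.01 to 1.25 CPM in the other 3 libraries. Pim2 was at 15.8 CPM against 46.3 to 48.8 CPM. Dab2 was at 1.67 CPM against 4.06 to 4.53 CPM. Hormad1 was at 100.7 CPM against 28.6 to 36.7 CPM. The same library had the highest Xist (82 CPM) and the lowest marker score (-2.09) of the 40kb libraries. Mitochondrial genes took 3.98% of its counts, against 1.86 to 2.48% in the other 11 RNA libraries, and its 10 most abundant genes 7.39%, against 5.55 to 6.65%.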

How the results depend on the processing

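The wild type of the other set, the marker score as a covariate, the crossing ratio without the edited bin, every alternative for the gene lists, the medians per chromosome and the wild types against each other, the X-linked tests without a filter, with an estimated correlation, with blocks, per clone sums or other sets of libraries, and leaving out libraries in the interaction and in the lost fragments were chosen after the data were seen. Of 2605 values under alternatives 1902 were unchanged, and of 68 results that answer a comparison 28 were so under all alternatives run and 40 changed under some. Unchanged means the same direction and side of the threshold for a single value, and a count within a set factor of the main count. For chromosome medians and crossing ratios it means a shift within the spread of autosomes or replicates. The cause was not tested for the results that changed. With 1 library left in a group, it is assumed to vary like the others. The 1070 genes called in the 40kb comparison became 1874 with DESeq2, 707 above a 1.2-fold change (glmTreat), 2476 in clone 1 alone, 530 in clone 2 alone, 3 with counts summed per clone, 0 against the wild type of the other set, 0 with the marker score as a covariate, and 0 to 1099 without single libraries. Of 47 named genes called there, 5 turned in direction with the covariate: Pcdh7 to 0.65, Ccdc80 to 0.39, Pappa to 0.20, Col1a2, itself part of the score, to 0.52 and Nr0b1 to -0.04. The 0 genes of the 70kb comparison became 3 with DESeq2 and 1 without a filter, in clone 1 alone or against all 4 wild-type libraries. The 0 genes of the interaction became 399 with DESeq2 and 10 without a filter, and were 0 to 1 without single libraries. X minus autosomes in the 40kb libraries was -0.091 with an estimated correlation (p = 0.125), -0.028 in clone 1, -0.036 without a filter, and -0.15 to -0.05 without single libraries. In the 70kb libraries it was 0.012 in clone 2, -0.049 against all 4 wild types and -0.054 against the other wild type, where camera called the X lower (p = 0.021 and 0.0266; p = 0.193 and 0.206 with an estimated correlation), and -0.04 to 0.008 without single libraries. Chromosome 8 minus autosomes, -0.078 in the 40kb libraries, was -0.155 in clone 1.

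Every gene list of the 40kb comparison had 0 calls with counts summed per clone, against the other wild type and with the marker score as a covariate. The fibroblast and trophoblast genes make up that score, so for these lists the covariate cannot decide. DESeq2 called 2 Tsix-side, 2 flanking, 9 naive, 1 2-cell-like, 2 germline, 6 p53, 4 Xist regulator, 1 cholesterol, 2 stress and 1 ribosomal gene. A mean of at least 50 counts gave 0 Tsix-side, 2 flanking, 1 naive, 2 endoderm, 4 fibroblast and 1 cholesterol gene. RLE scaling gave 2 flanking genes and upper-quartile scaling 1 cholesterol gene. No filter gave 4 p53 and 1 cholesterol gene. Above a 1.2-fold change there were 0 flanking, 0 naive, 2 endoderm, 5 fibroblast and 0 housekeeping genes. The 6 libraries of the set alone gave 1 naive, 0 germline, 4 p53 and 0 glycolysis genes. Clone 1 alone gave 2 flanking, 10 naive, 6 formative, 1 2-cell-like, 12 imprinted, 3 germline, 4 Xist regulator, 1 Y-linked, 2 glycolysis, 2 cholesterol, 3 stress, 21 ribosomal and 2 housekeeping genes, and 1 imprinted gene in the 70kb comparison. Clone 2 alone gave 2 Tsix-side, 0 formative, 2 endoderm, 1 mesoderm, 0 neural, 2 fibroblast, 0 germline, 5 p53 and 0 glycolysis genes. All 4 wild types gave 2 Tsix-side, 2 flanking, 0 germline, 1 Y-linked, 1 cholesterol and 2 stress genes. Without single libraries the lists had 0 to 3 Tsix-side, 0 to 4 Xist-side, 0 to 1 flanking, 0 to 1 naive, 0 to 2 formative, 0 to 4 endoderm, 0 to 4 mesoderm, 0 to 1 neural, 0 to 2 2-cell-like, 0 to 7 fibroblast, 0 to 5 trophoblast, 0 to 7 imprinted, 0 to 2 germline, 0 to 3 p53, 0 to 3 Xist regulator, 0 to 1 glycolysis, 0 to 1 stress and 0 to 1 housekeeping genes.

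In RNA, replicate numbers pair the samples only in the 70kb set, where they go with the B code and the replicate block left 0 genes. In 5C, XiteE-inv and wild type of the same number also share the B code (correlation 0.495). In the 40kb set (0.039, -0.165 and 0.222) and in XiteE-del, XiteC-del and XiteC-inv (0.062, -0.132 and 0.161) the samples share only a number. The block by title number gave 1447 genes in the 40kb comparison, 2 flanking, 5 naive and 2 neural genes, and 1 pair in XiteC-inv. The block by B code gave 357 genes, 2 Tsix-side, 0 flanking, 1 endoderm, 1 mesoderm, 2 neural, 0 fibroblast, 1 trophoblast, 0 germline, 1 Xist regulator and 0 housekeeping genes. In 5C that block gave 2 pairs in XiteE-del, 11 in XiteC-del and 33 in XiteC-inv, and 3, 8 and 15 domain blocks. RAP pull-downs were not paired (0.133, 0.114 and 0.007), and their block gave 107 windows.

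The 5C pairs were 5 with 15 kb bins and 7 with DESeq2 in XiteE-del, 7 with DESeq2 in XiteE-inv, and 4 with distance scaling, 2 with coverage correction and 9 in the B100 libraries alone in XiteC-del. In XiteC-inv the 4 pairs became 2 with 15 kb bins, 0 with 60 kb bins, 0 with TMM, 0 with at least 50 counts, 27 with DESeq2, 13 with distance scaling, 7 with coverage correction, 30 in the B100 libraries alone and 0 to 2 without single libraries. The crossing ratio of XiteE-del was 1.19 over 90 kb and 1 over 300 kb. In XiteC-del it was 1.48 over 300 kb and 1.94 without the edited bin, and in XiteC-inv 1.29 and 1.2. Lost fragments in XiteE-inv were 0 to 9 without single libraries. The 109 RAP windows of the 40kb clone became 3 when centred and 11 to 129 without single libraries.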

Other observations

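Of the tests below, those of the 40kb allele, of 1 scaling factor per library, of the input profile with the input of another line, of Xist RNA in the pull-down clone, of the 5C library code, of the XiteC sequence, of fragment recovery in each XiteC genotype and of the orders within replicate numbers were chosen after the result was seen, as were the fragment contacts, the distance classes and the nearest X genes. The contacts of the Xite fragments themselves shifted in XiteC-inv. The XiteE fragments had 55.4% and 56.8% of their counts on the Tsix side in wild type and 30.4% and 30.2% in XiteC-inv. On the Xist side the XiteE fragments had 9.72% and 10.1% in wild type, 22.2% and 22.9% in XiteC-inv, and 17.4% and 17.2% in XiteC-del. The XiteC fragment had 11.1% and 15.3% on the Xist side in wild type and 25.7% and 23.6% in XiteC-inv.

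Windows with more Xist pull-down in the 40kb clone lay at all distance classes from 2 Mb on. The median log2 fold change was 0.25 for the windows 1 Mb from the window of the Xic (0 of 2 called in limma), which itself was at -2.0. Farther away the median was 1.27 at 2 to 5 Mb (6 of 8 called), 0.98 at 6 to 20 Mb (13 of 30), 1.33 at 21 to 50 Mb (43 of 60) and 1.23 at 51 to 100 Mb (46 of 63). Centred on the median of each library, 3 windows were called in all. Among X-linked genes in the 40kb libraries, the 10 nearest to Xist in gene order had a median log2 fold change of -0.675, with 8 of 10 lower and 4 called lower. In the 70kb libraries the nearest 10 had a median of -0.324, with 7 of 10 lower and 0 called lower. The nearest 25 differed from the other X-linked genes by -0.137 in the 40kb and -0.002 in the 70kb libraries (permutation test, 100000 resamples, p = 0.259 and 0.945). The 40kb clones differed from each other in 11 genes (edgeR), and Xist was higher in clone 1 by 1.83 on the log2 scale (SE 0.40, adjusted p = 0.0927).

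The genes lower in the 40kb libraries may reflect cells of other types in the wild-type cultures of that set. In the 6 libraries of the 70kb set, which lack the 40kb allele, the mean level of the 928 lower genes outside the marker lists followed the marker score (r = 0.998, exact permutation p = 0.00139; rho = 1, p = 0.00278; r = 0.997 without the 2 farthest libraries; p = 0.0278 for both over the 36 orders within replicate numbers, the smallest they allow). The slope predicted a fall of -1.56 on the log2 scale where -2.05 was seen. The genes were chosen as lower in the 40kb comparison, which enlarges the fall seen. The 40kb scores (-2.093 to -0.681) also lie below those that the slope was fitted on (-0.667 to 1.83). The gap therefore cannot show whether the score leaves a part of the fall open. Whether the library code plays a part is not settled. Median differences were -1.77 within code B2 and -1.70 within B6, but the genes were chosen as lower in these same libraries, which favours such values. With the code as a block 256 of the 1070 calls were kept, and all 1070 kept their sign (edgeR). That block takes out the 40kb libraries that share a code with no other library, which alone can lower the count. An effect of the 40kb allele stays open: against the other wild type the lower genes had a median of -1.37 with 0 called (edgeR, 2134 at an unadjusted p under 0.05), in a comparison that shares the allele libraries, and of the 25 markers 15 were over 1 CPM in the 40kb libraries and 21 in their wild type.

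The Xist pull-down of the 40kb clone was higher outside the window of the Xic and lower in it. A single scaling factor per library moves all windows alike, so it cannot give both. Centred on the median, the window of the Xic still differed by -3.17 on the log2 scale, which restates this pattern. Background with the profile of the input would leave no shared structure across windows. Both pull-downs of the clone correlated at r = 0.704 across windows, which are not independent replicates. With 1 of them over the input of another line r was 0.643 to 0.715. The 40kb pull-downs also correlated with those of wild type (r = 0.321 and 0.328), and the wild-type pull-downs with each other (0.239). Some structure was thus shared with wild type, and these values speak only to background with the profile of the input. More Xist RNA in this clone (log2 fold change 6.33, SE 0.52) is a candidate explanation. The height of the rise still rests on the input scaling that both pull-downs share.

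Contacts across the border were a larger share in XiteC-del and XiteC-inv. The library code is argued against, since the lowest XiteC library exceeded the wild-type library of the same code by 3.8 percentage points. Recovery of fragments at the edited site is argued against in XiteC-del, at 1.94 times wild type without the edited bin. The first bound written for recovery asked for at least 1.2 times without that bin in both genotypes. XiteC-inv, at a value that rounds to 1.2, lay just under it, so that test was undecided. In XiteC-inv single fragments of that bin, where recovery cancels, were tested instead. Contacts across the border over those on the own side lay above both wild-type libraries in 7 of 7 fragments. The median was 3.18 times for the lowest XiteC-inv over the highest wild-type library, which argues against recovery there. The same median was 1.01 in XiteC-del and 1.09 in XiteE-del, with 4 of 7 fragments above wild type in each. The lowest XiteC library lay 2.7 percentage points above the highest other library, which restates the pattern, so a role of the XiteC sequence stays open and untested.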
